A study of Arabidopsis thaliana with 12 samples.

How the data were processed

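RNA from seeds of 2 genotypes, Ler and abi3-5, was biotin-labelled and hybridised to 12 arrays, with 3 arrays in each of 4 groups. The deposited value table holds the authors' processed values on a log2 scale, as judged from their range of 1.31 to 14.7 and from their distribution. The background correction, normalization and summarization that the authors used are not given in the sources used here. Array medians over the tested genes lay between 5.45 and 5.65, and values were not centred per gene. Groups and replicate numbers were taken from the sample titles. The titles do not say whether replicates came from separate plants, so p-values measure the spread between these samples, which may be technical. Pearson's r between arrays of a group lay between 0.972 and 0.994. No column was left unmapped.

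The table has 38408 features. The platform annotation names exactly 1 gene for 16722 of them and several genes for 759, and 20927 features are unnamed here. Symbols were updated by gene identifier through the reference gene table of assembly TAIR10.1, which matched 16574 of the 16722, and the other 148 kept the annotation's symbol. Where a gene had several features, as 146 genes did, the feature with the highest mean over all 12 arrays was kept, which left 16550 genes. No flag for signal over background was used. The 25th percentile of mean levels was 3.89, and differences of genes near the low or the high end of the scale can be understated.

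limma 3.58.1 in R 4.3.3 fitted 4 group means to all 12 arrays, with moderated tests (eBayes without trend or robust option), two-sided, and Benjamini-Hochberg adjustment over the 16550 genes. Genes with an adjusted p under 0.05 were counted by sign. The 5 contrasts were abi3-5 against Ler in developing and in blotter seeds, blotter against developing seeds in Ler and in abi3-5, and their interaction. On simulated data with 200 changed genes among 16550, for the comparison of developing seeds, the fit recovered 61.2% of genes changed by 1 log2 unit and 94.6% of those changed by 2, and 5.35% of calls were false.

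Before the data were examined, 22 gene lists were fixed. Of these, 12 had 3 or more measured members and were tested with camera at a preset correlation of 0.01, adjusted over the lists within each contrast. Camera with an estimated correlation and fry were alternatives. The measured members numbered 3 of 18 for gibberellin metabolism and signalling, all of them GID1 receptor genes, 4 of 20 for oil mobilisation, 3 of 8 for other late seed genes, 4 of 16 for seed coat, 3 of 9 for endosperm and 3 of 9 for fruit wall markers. For 7 lists with 1 or 2 members the members alone are given. These are seed maturation regulators, fatty acid and oil synthesis, chlorophyll synthesis, chlorophyll breakdown, cell division, jasmonate and wound response, and hypoxia response. The lists of abscisic acid synthesis and catabolism, clade A PP2C phosphatases and raffinose synthesis had 0 measured members and were not analysed here. A ribosomal protein list was to be added only if the reference described such genes, and it was not used. The single measured jasmonate gene, PDF1.2, passed in none of the 5 contrasts (-0.06 between genotypes in developing and -0.59 in blotter seeds), but was lower in abi3-5 blotter seeds with the replicate number as a block. GID1B was higher in developing abi3-5 seeds (1.11, adjusted p = 0.0265), a call lost without any 1 of 4 arrays (adjusted p = 0.0502 to 0.112, the last without abi3-5 developing replicate 1). The single chlorophyll breakdown gene, NOL, was higher in developing abi3-5 seeds (0.67) and is given for Ler on the blotter with that comparison. Of the fatty acid and oil synthesis list FATB passed in none of the contrasts, and FaTA is given with the comparisons. The other hypoxia gene, AT3G10040, passed in none. For seed coat markers the median and mean differed in sign in 4 contrasts that did not pass (for example -0.13 and 0.31 between genotypes in blotter seeds), as they did for endosperm markers in both blotter contrasts and for fruit wall markers in Ler on the blotter.

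Genes were named by a rule also fixed before the data were examined. It takes the 6 largest positive and 6 largest negative differences past the threshold in each contrast whose 2 groups do not overlap (for the interaction, past the threshold only), up to 2 members per list past the threshold with the largest difference, and every regulator of seed maturation past it. It also asked for ABI3 in every sample and for other regulators that missed the threshold, which were not analysed here. A subset of the genes it gave is printed. Genes named otherwise are said to be so.

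Replicate numbers are shared by the groups. Deviations from the group means were correlated between arrays of the same number. In 3 of the 4 comparisons between groups all 3 correlations were over 0.1, namely 0.19, 0.26 and 0.36 for the genotypes in blotter seeds, 0.28, 0.14 and 0.39 for the blotter in Ler and 0.18, 0.11 and 0.24 for the blotter in abi3-5. The numbers may pair those arrays, as read from the data and not from a stated batch. Deviations in a group of 3 sum to 0. A shared deviation of the arrays numbered 3 alone can therefore make all 3 correlations positive. Printed counts, standard errors and adjusted p are from the fit without the number, unless said otherwise. A fit with the number as a block was an alternative throughout.

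Other alternatives were a fit on the groups compared alone, eBayes with trend and robust options, array weights, quantile normalization of the deposited values, centring each array on its median, dropping genes below the 25th percentile or the median of mean level, every feature of the table, the mean of a gene's features, and leaving out each array. Leaving out the 4 arrays numbered 3 was added after the data were seen. The overlap of calls between comparisons was set against independent lists, and the pair of comparisons with shared arrays against 100 simulations of unchanged groups.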

Results

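Transcript levels were measured on 12 single-colour arrays in developing seeds of Arabidopsis thaliana. Seeds came from the wild-type accession Landsberg erecta (Ler) and from abi3-5, a mutant of ABI3, a transcription factor of seed maturation. Seeds of each genotype were either collected 15 to 16 days after flowering and frozen, or collected 14 to 15 days after flowering, kept for 1 day on moist blotter paper and then frozen. These are called developing seeds and blotter seeds here. No seeds were frozen at 14 to 15 days after flowering, so the state before the blotter was not measured. Where transcripts are said to rise, fall or change on the blotter, blotter seeds are compared with developing seeds of about the same total age. The blotter and the earlier collection cannot be told apart in this layout. Each of the 4 groups held 3 arrays, and this number limits the precision of every value. The layout asks which transcripts differ between the genotypes in each kind of seed, which differ after the blotter in each genotype, and whether the blotter difference depends on the genotype. The series concerns direct and indirect targets of ABI3. Levels of 16550 genes were tested, and differences are given on the log2 scale with their standard errors (SE). The ABI3 transcript was not analysed here, so the genotype labels were not checked by it.

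Transcripts of the desiccation-linked LEA and dehydrin proteins were lower in developing abi3-5 seeds than in developing Ler seeds. Of the 23 measured members of this list of 34, 15 were lower, 0 were higher and 8 did not pass the threshold. Some of those that did not pass lay near the low end of the scale, where a fall can be missed. AT4G13230 (3.69 in Ler and 3.61 in abi3-5) lay under the 25th percentile of mean levels (3.89) in all groups. Another, AT3G02480, lay high (12.76 and 13.21). Adjusted over the list alone, 17 were lower and 1 was higher, and 1 was also higher with the replicate number as a block. AT2G42560 fell from 11.95 ± 0.29 (SD, n = 3) in Ler to 4.36 ± 0.23 (SD, n = 3) in abi3-5, the largest negative difference of all genes named by the rule (log2 difference -7.59 ± 0.18 SE, adjusted p = 3.77e-11). AT3G53040, another LEA gene, differed by -5.45 ± 0.19. All 4 measured oil body protein genes of 11 were lower, both over all genes and adjusted over the list alone, among them the oleosin genes AT3G18570 (-3.67 ± 0.32) and OLEO3 (-3.26 ± 0.31). Of 5 measured seed storage protein genes of 13, 3 were lower on either count, including the cupin genes AT2G18540 (-3.44 ± 0.26) and AT1G03890 (-1.97 ± 0.40).

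Further gene groups were lower or higher in developing abi3-5 seeds. Of 10 measured small heat shock protein genes, 4 were lower and 6 did not pass, and 6 were lower when adjusted over the list alone. AT1G52560 (-2.79 ± 0.32) and AT1G53540 (-1.92 ± 0.30) led this list. Replicates 1 and 2 carried the difference: relative to the developing Ler mean, the mean of the list lay at -1.70, -1.58 and -0.36 in replicates 1, 2 and 3 of abi3-5 and at 0.26, 0.24 and -0.50 in those of Ler, so that among the arrays numbered 3 abi3-5 was not below Ler. Without abi3-5 developing replicate 3, as without all arrays numbered 3, 8 heat shock genes were lower. Both measured regulators of seed maturation, out of 24 listed, were lower. The bZIP transcription factor gene EEL differed by -1.83 ± 0.30 (adjusted p = 0.000653) and BZIP53 by -0.68 ± 0.19 (adjusted p = 0.0181). The BZIP53 call was lost without Ler developing replicate 3 (-0.52, adjusted p = 0.0718) and without abi3-5 developing replicate 1 (-0.52, adjusted p = 0.0947). Nuclear-encoded photosynthesis genes were higher: 5 of 7 measured members of 40 passed on either count, among them PSBW (3.13 ± 0.33) and PSAN (2.02 ± 0.29), which encode photosystem subunits. Both measured chlorophyll synthesis genes were higher, PORB by 4.33 ± 0.39 and CHLM by 2.76 ± 0.20. The expansin genes EXPA9 (3.70 ± 0.29) and EXPA20 (2.39 ± 0.26) were the 2 of 4 measured cell wall loosening genes that rose. In the oil mobilisation list 3 of 4 measured genes rose, led by ICL, the isocitrate lyase gene of the glyoxylate cycle (1.11 ± 0.16). PRL, a subunit gene of the replicative helicase, was higher (2.13 ± 0.37), and PDC2, a pyruvate decarboxylase gene, was lower (-1.65 ± 0.15). FaTA, an acyl carrier protein thioesterase gene, was lower (-1.38 ± 0.20).

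The largest positive differences in developing seeds, by the naming rule, were those of NAI2, AT2G27140, PYK10, AT1G47395, AT2G37660 and AT5G39080. NAI2 and PYK10 encode proteins of endoplasmic reticulum bodies. NAI2 averaged 12.29 ± 0.30 (SD, n = 3) in abi3-5 and 5.13 ± 2.21 (SD, n = 3) in Ler, and AT2G27140 averaged 9.58 ± 0.34 against 4.08 ± 0.12. The Ler value of NAI2 rested on unequal arrays, with 7.61 in replicate 1 against 3.35 and 4.42 in the others. The largest negative differences were those of AT2G42560, AT3G60730 (-6.98 ± 0.24), AT2G25890 (-6.70 ± 0.35), AT3G56350 (-6.59 ± 0.35), AT2G21720 (-6.55 ± 0.15) and the beta-glucosidase gene BGLU19 (-6.54 ± 0.34).

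In all, 1886 genes were higher and 1882 lower in developing abi3-5 seeds by limma, and 980 and 786 of them by 2-fold or more. The camera test, which compares a list with all other genes, called the LEA list (median -1.68, adjusted p = 5.83e-12), oil body proteins (-2.88, adjusted p = 0.000213), heat shock proteins (-1.22, adjusted p = 0.0071) and seed storage proteins (-1.32, adjusted p = 0.0117) lower. It called photosynthesis (1.74, adjusted p = 0.000213), oil mobilisation (0.56, adjusted p = 0.00956) and cell wall loosening (1.33, adjusted p = 0.00956) higher. None of these list calls held with an estimated correlation between genes, with an adjusted p = 0.0851 for the LEA list, 0.317 for heat shock and storage proteins, 0.207 for oil mobilisation and 0.206 for the oil body, photosynthesis and cell wall lists. The cell wall call rested on 4 measured genes of 15, 3 of them expansin genes. Of all 13 tested genes with an EXPA symbol, a family examined after the data were seen, 2 were higher and 3 lower (median -0.32), and of 9 with an XTH symbol 1 was higher and 2 lower (median -0.19), and neither family passed (adjusted p = 0.878 and 0.888). Other late seed genes did not pass camera as a list (adjusted p = 0.144), but did without abi3-5 blotter replicate 1 (adjusted p = 0.00797), and 1 of 3, ATOEP16-2, was lower (-1.51 ± 0.43, adjusted p = 0.0211). The ATOEP16-2 call was lost without any 1 of 5 arrays (adjusted p = 0.0503 to 0.0848, the last without abi3-5 developing replicate 1). Markers of seed coat, endosperm and fruit wall did not pass camera (adjusted p = 0.171, 0.499 and 0.396). The endosperm markers lay near or under the 25th percentile of mean levels (3.89) in all groups, where a difference can be missed. Their means in developing Ler and abi3-5 seeds were 2.51 and 2.37 for AGL62, 3.91 and 3.97 for MPC and 4.43 and 3.98 for PHE1. The seed coat marker BAN and the fruit wall marker JAG lay as low, while ARA12 (6.08 and 7.62) and YAB3 (9.50 and 9.65) lay higher. With fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, seed coat markers were higher (adjusted p = 0.00352), among them ARA12 (1.54 ± 0.29) and AT2G22900 (0.68 ± 0.15). The endosperm marker PHE1 was lower (-0.45 ± 0.14, adjusted p = 0.0383), a call lost with only the 2 groups compared (adjusted p = 0.0587), with the trend and robust options (0.0703), under quantile normalization (0.154) and without any 1 of 6 arrays (0.0505 to 0.145, the last without abi3-5 developing replicate 1).

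**Figure D1:**
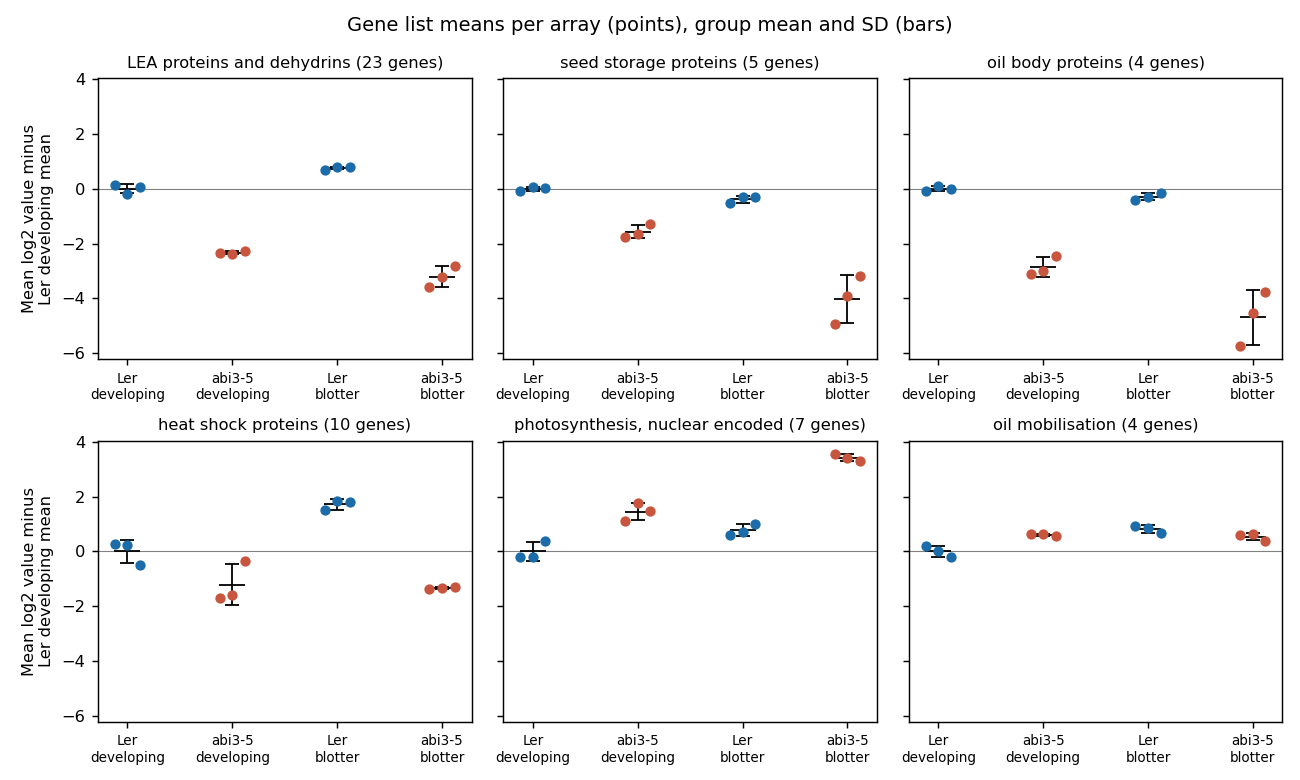
Mean log2 value of the measured members of 6 gene lists on each array, minus the Ler developing mean, on the y axis, for the 4 groups on the x axis. Points are arrays, and bars give the mean and SD of 3 arrays. The mean of the LEA list lay at -2.33 in developing abi3-5 seeds, at 0.75 in Ler blotter seeds and at -3.20 in abi3-5 blotter seeds.

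In blotter seeds the LEA transcripts were again lower in abi3-5 than in Ler. Of 23 measured members 18 were lower and 1 was higher, on either count, with a median difference of -4.98. AT2G42560 averaged 12.87 ± 0.07 (SD, n = 3) in Ler and 5.20 ± 0.21 (SD, n = 3) in abi3-5 (log2 difference -7.67 ± 0.18 SE, adjusted p = 2.80e-11), and the LEA gene M17 differed by -6.62 ± 0.76. All 5 measured storage protein genes, all 4 oil body genes and all 3 other late seed genes were lower, also when adjusted over the list alone. AT2G18540 (-5.83 ± 0.26), AT1G03890 (-5.48 ± 0.40), AT3G18570 (-5.79 ± 0.32) and AT1G48990 (-4.66 ± 0.53) led these lists. Of 10 small heat shock protein genes 9 were lower, such as AT1G52560 (-6.42 ± 0.32) and AT1G53540 (-5.04 ± 0.30). The remaining one, AT4G21870, was higher by 2.81 (adjusted p = 0.00409). Its abi3-5 arrays were unequal, with 6.92 ± 1.99 against 4.11 ± 0.27 in Ler (SD, n = 3 each). AT2G03850 was the LEA gene that was higher (0.86 ± 0.21). These 2 genes were singled out after their values were seen.

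Photosynthesis transcripts were higher in abi3-5 blotter seeds, with 6 of 7 measured members past the threshold on either count. LHB1B2, which encodes a light-harvesting chlorophyll-binding protein, averaged 11.50 ± 0.35 against 6.38 ± 0.20 in Ler (SD, n = 3 each). PSAN differed by 3.97 ± 0.29, and PORB, a protochlorophyllide reductase gene, by 5.91 ± 0.39. EXPA9 was higher by 4.95 ± 0.29, and 3 of 4 cell wall loosening genes were higher, or 4 when adjusted over the list alone. The gibberellin receptor genes went both ways: GID1A (-2.06 ± 0.15) and GID1C (-1.55 ± 0.28) were lower and GID1B, named after its value was seen, was higher by 1.10 (adjusted p = 0.0170), a call lost without replicate 1 of either genotype's blotter seeds. These 3 receptor genes are all that was measured of the 18 listed genes of gibberellin metabolism and signalling. They did not pass camera as a list (adjusted p = 0.247), nor did oil mobilisation genes (adjusted p = 0.610), whereas fry called both lower (adjusted p = 1.31e-05 and 0.0283). EEL (-2.75 ± 0.30), BZIP53 (-1.15 ± 0.19), PDC2 (-3.42 ± 0.15) and AIM1 (-0.96 ± 0.14), a gene of peroxisomal beta-oxidation, were lower, and PRL was higher by 3.54 ± 0.37. FaTA, lower in developing abi3-5 seeds, was higher in abi3-5 blotter seeds (0.59 ± 0.20, adjusted p = 0.0332). This call was lost under quantile normalization (adjusted p = 0.101) and median centring (0.0791), and without Ler blotter replicate 1 (0.120) or abi3-5 blotter replicate 2 (0.113) or 3 (0.0646).

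By the naming rule, AT1G06360 (6.21 ± 0.46), PORB, AT3G20370 (5.56 ± 0.54), CP1 (5.47 ± 0.38), AT5G45650 (5.38 ± 0.48) and the photosystem I subunit gene PSAE-1 (5.25 ± 0.31) had the largest positive differences in blotter seeds. The largest negative differences were those of AT2G42560, AT5G43770 (-7.15 ± 0.18), AT2G25890 (-7.09 ± 0.35), AT3G58450 (-6.93 ± 0.21), BGLU19 (-6.91 ± 0.34) and AT2G21720 (-6.76 ± 0.15). In all, 3023 genes were higher and 3214 lower in abi3-5, and 1900 and 1409 of them by 2-fold or more. Higher calls made up 48.5% of the calls on the deposited scale and 37.9% after centring each array on its median. Centring shifted the median of all genes by -0.12. The medians of the LEA, heat shock, storage, oil body and photosynthesis lists differed by more than 2 log2 units.

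Camera called the LEA (adjusted p = 2.01e-13), heat shock (5.20e-05), oil body (0.000237), storage (0.000301) and other late seed lists (0.0162) lower in abi3-5 blotter seeds, and photosynthesis (3.93e-05) and cell wall loosening (0.00427) higher. With an estimated correlation none of these calls held, with an adjusted p = 0.0619 for the LEA list, 0.156 for photosynthesis, 0.179 for the heat shock, oil body, storage and cell wall lists and 0.286 for other late seed genes. Over all 13 tested EXPA genes, a family examined after the data were seen, 3 were higher and 2 lower (median -0.12, adjusted p = 0.555), and over 9 XTH genes 4 were higher and 1 lower (median 0.19, adjusted p = 0.482). Fruit wall markers did not pass camera as a list (adjusted p = 0.193) but were higher with fry (adjusted p = 0.00986), and 2 of 3 were higher, ALC (1.38 ± 0.26) and YAB3 (0.56 ± 0.20, adjusted p = 0.0459). The YAB3 call was lost under median centring (adjusted p = 0.0848), over every feature (0.0637) and without any 1 of 8 arrays (0.0532 to 0.159, the last without abi3-5 blotter replicate 1), which leaves 1 of 3. Seed coat and endosperm markers did not pass camera either (adjusted p = 0.531 and 0.882). Fry called seed coat markers higher (adjusted p = 0.000625), although their median was -0.13, and AT2G22900 was the 1 of 4 that was higher (1.89 ± 0.15).

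**Figure D2:**
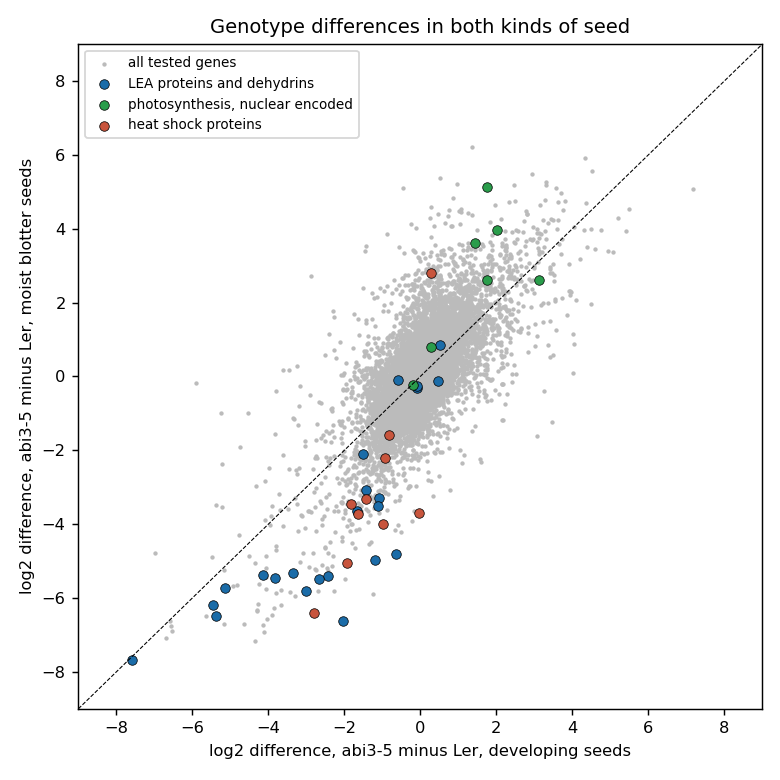
Log2 difference between abi3-5 and Ler for each tested gene in developing seeds (x axis) and in blotter seeds (y axis), with 3 gene lists in colour and the line of equal differences dashed. Pearson's r across the genes was 0.71.

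After 1 day on the blotter, Ler seeds held more small heat shock protein transcripts than developing Ler seeds. Of 10 measured members 6 rose and 4 did not pass, or 7 rose when adjusted over the list alone. AT1G52560 went from 9.19 ± 0.36 to 11.75 ± 0.19 (SD, n = 3 each) with a log2 difference of 2.56 ± 0.32 SE (adjusted p = 8.96e-05), and AT1G53540 rose by 2.80 ± 0.30. In the LEA list 9 of 23 members rose and none fell, or 10 rose when adjusted over the list alone, among them M17 (3.85 ± 0.76) and M10 (2.11 ± 0.32), and with array weights 1 fell. By limma none of the 5 storage, 4 oil body or 3 other late seed genes passed in Ler, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2 lower storage genes and 0 genes of the other 2 lists, and camera did not call these lists either (adjusted p = 0.757, 0.595 and 0.964). Other settings called some: 2 storage genes and 1 oil body gene were lower with only the 2 groups compared, with array weights and without abi3-5 blotter replicate 3, 1 storage gene was lower without abi3-5 blotter replicate 1, and 1 storage gene was higher with the replicate number as a block or with array weights. Without all arrays numbered 3, 1 storage gene was higher and 1 lower. Some of the storage and other late seed genes lay near the highest value of the scale, 14.7. Means in developing and blotter Ler seeds were 14.20 and 14.31 for PAP85, 14.19 and 13.31 for AT1G03890 and 13.25 and 13.31 for BETA-VPE. Others lay lower, such as the storage gene AT2G18540 at 10.89 and 11.38. Differences of the brightest genes may be understated, which was not tested. The receptor genes GID1C (1.67 ± 0.28) and GID1A (1.12 ± 0.15) rose, and 3 of 4 oil mobilisation genes rose, led by AIM1 (1.21 ± 0.14) and ICL (0.96 ± 0.16).

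In Ler, 3 of 7 photosynthesis genes rose on the blotter, including PSBW (1.91 ± 0.33) and LHCB4.1 (1.84 ± 0.28), on either count, and CHLM rose by 1.69 ± 0.20. NOL, a chlorophyll b reductase gene, differed by 0.53 ± 0.16 (adjusted p = 0.0345). Its adjusted p was 0.1004 and 0.0902 without replicates 1 and 2 of developing Ler, 0.106 and 0.125 without replicates 1 and 2 of Ler blotter seeds, 0.0522 without abi3-5 developing replicate 2, and 0.0586 with only the 2 groups compared. FaTA fell by 2.90 on the log2 scale. PDC2 rose (0.81 ± 0.15), as did the seed coat marker ARA12 (1.74 ± 0.29). By the naming rule the largest rises were those of the defensin gene PDF1.4 (7.21 ± 0.46), AT5G24490 (4.51 ± 0.29), AT1G68240 (4.46 ± 0.45), AT1G65500 (4.19 ± 0.41), AT2G36970 (4.03 ± 0.36) and the glycosyltransferase gene UGT73B4 (4.02 ± 0.26). The largest falls were those of the expansin gene EXPA15 (-6.09 ± 0.33), AT5G22810 (-6.05 ± 0.32), AT2G27570 (-5.60 ± 0.30), AT5G16240 (-5.42 ± 0.26), AT1G19900 (-5.24 ± 0.29) and FOLB3 (-4.95 ± 0.25).

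In all, 1488 genes rose and 1464 fell in Ler on the blotter, and 598 and 803 of them by 2-fold or more. Camera called heat shock proteins (median 1.94, adjusted p = 2.50e-05), LEA proteins (0.51, adjusted p = 0.000199), oil mobilisation (0.88, adjusted p = 0.00243), the 3 gibberellin receptor genes (1.12, adjusted p = 0.0236) and photosynthesis (0.46, adjusted p = 0.0236) higher. With an estimated correlation none held, with an adjusted p = 0.377 for photosynthesis and 0.220 for the others. The photosynthesis call was also lost without Ler developing replicate 1 (adjusted p = 0.0646), without Ler blotter replicate 3 (0.0558) and among genes above the median level (0.0909). Seed coat, endosperm and fruit wall markers did not pass as lists with camera (adjusted p = 0.872, 0.964 and 0.964) or fry (0.210, 0.959 and 0.863).

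In abi3-5 seeds, photosynthesis transcripts rose on the blotter and storage protein transcripts fell. All 7 measured photosynthesis genes rose, also when adjusted over the list alone. LHB1B2 went from 8.00 ± 0.76 to 11.50 ± 0.35 (SD, n = 3 each; log2 difference 3.50 ± 0.36 SE, adjusted p = 6.14e-05) and PSAN rose by 2.41 ± 0.29. PORB (2.14 ± 0.39), CHLM (1.40 ± 0.20), EXPA8 (1.98 ± 0.46) and PRL (1.86 ± 0.37) rose as well. In all, 3 of 4 cell wall loosening genes rose on either count, EXPA8, EXPA9 and XTH33 (1.58 ± 0.46, adjusted p = 0.0372). With only the 2 groups compared in the fit EXPA8 had an adjusted p = 0.0529 and XTH33 0.105, which leaves 1 of 4. The XTH33 call was also lost over every feature (adjusted p = 0.0706) and without any 1 of 6 arrays (0.0505 to 0.163, the last without abi3-5 developing replicate 3). Of 5 storage protein genes 4 fell, or 5 when adjusted over the list alone, with AT1G03890 going from 12.22 ± 0.47 to 7.84 ± 1.04 (SD, n = 3 each). AT2G28490 fell by 2.77 and the oleosin gene AT3G18570 by 2.63 on the log2 scale, and 3 of 4 oil body genes fell, or 4 when adjusted over the list alone.

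In the LEA list of abi3-5 seeds 11 members fell, 1 rose and 11 did not pass on the blotter, or 11 fell and 3 rose when adjusted over the list alone. The gene that rose was AT2G42560 (0.84 ± 0.18), singled out after its value was seen, and 2 rose without abi3-5 blotter replicate 3, Ler developing replicate 1 or Ler developing replicate 2. AT3G15670 (-3.18 ± 0.20) and AtLEA4-1 (-2.60 ± 0.33) changed most, and EEL differed by -1.60 ± 0.30. GID1A (-0.81 ± 0.15), PDC2 (-0.96 ± 0.15) and FaTA (-0.93 ± 0.20) were lower, and the seed coat marker AT2G22900 was higher (0.95 ± 0.15). By limma none of 4 oil mobilisation genes passed, and 0 did at an unadjusted p under 0.05. By the naming rule the largest rises were those of AT5G26260 (4.76 ± 0.43), AT1G06360 (4.69 ± 0.46), AT5G45650 (4.56 ± 0.48), PDF1.4 (4.49 ± 0.46), AT2G45180 (4.38 ± 0.51) and AT5G45950 (4.23 ± 0.30). The largest falls were those of AT1G19900 (-5.45 ± 0.29), AT2G41390 (-5.34 ± 0.56), the cytochrome P450 gene CYP78A9 (-4.39 ± 0.29), AT1G03890 (-4.39 ± 0.40), AT3G04190 (-4.25 ± 0.20) and AT1G62220 (-4.24 ± 0.65).

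In all, 1074 genes rose and 1082 fell in abi3-5 seeds on the blotter, and 577 and 540 of them by 2-fold or more. On abi3-5 blotter replicate 3 the 35 measured storage, oil body, LEA and other late seed genes lay 0.64 above their group means at the median. Without abi3-5 blotter replicate 1 these counts were 650 and 714, and without abi3-5 developing replicate 3 the first was 701. Camera called photosynthesis (median 1.93, adjusted p = 8.21e-10) and cell wall loosening (1.52, adjusted p = 0.0184) higher, and storage proteins (-2.57, adjusted p = 1.48e-06), oil body proteins (-1.94, adjusted p = 0.000318), LEA proteins (-0.73, adjusted p = 0.000318) and other late seed genes (-1.52, adjusted p = 0.00803) lower. With an estimated correlation none held, with an adjusted p = 0.0511 for photosynthesis, 0.190 for storage proteins, 0.248 for other late seed genes and 0.217 for the others. Heat shock genes did not pass as a list (adjusted p = 0.398), with AT4G21870 higher by 2.85 and AT1G52560 lower (-1.06 ± 0.32, adjusted p = 0.0436) among 10. With only the 2 groups compared neither passed (adjusted p = 0.0635 and 0.104), and the AT1G52560 call was also lost over every feature (0.0780) and without any 1 of 9 arrays (0.0507 to 0.180, the last without abi3-5 developing replicate 3). Of 3 other late seed genes 2 were lower, BETA-VPE (-1.52 ± 0.32) and AT1G04560 (-2.08 ± 0.61, adjusted p = 0.0396). The AT1G04560 call was lost with only the 2 groups compared (adjusted p = 0.132), under quantile normalization (0.0626), over every feature (0.0747) and without any 1 of 9 arrays (0.0520 to 0.119, the last without abi3-5 developing replicate 3). The 3 gibberellin receptor genes did not pass camera (adjusted p = 0.264) but were lower with fry (adjusted p = 0.00841). The cell wall call was also lost among genes above the median level (adjusted p = 0.0704) and over every feature (0.0692), and neither the 13 EXPA genes (3 higher, 1 lower, median 0.06, adjusted p = 0.643) nor the 9 XTH genes (2 higher, 0 lower, median 0.22, adjusted p = 0.372) passed. Seed coat, endosperm and fruit wall markers did not pass camera (adjusted p = 0.398, 0.542 and 0.264), and fry called seed coat markers higher (adjusted p = 0.0222), although their median was -0.03.

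The blotter difference depended on the genotype for some LEA, heat shock, storage and oil body genes. The interaction, which is the blotter difference in abi3-5 minus that in Ler, was negative for 13 of 23 LEA genes and for 5 of 10 heat shock genes, or 15 and 7 when adjusted over the list alone, where 1 heat shock gene was positive. M10 (-4.16 ± 0.46, adjusted p = 0.000172), M17 (-4.58 ± 1.08), AT2G29500 (-3.67 ± 0.54) and AT1G52560 (-3.62 ± 0.45) led these lists. M10 went from 10.33 ± 0.39 to 12.44 ± 0.21 in Ler and from 9.70 ± 0.56 to 7.64 ± 0.62 in abi3-5 (SD, n = 3 each). The interaction was also negative for 3 of 5 storage genes, or 4 adjusted over the list alone, with AT1G03890 at -3.50 ± 0.57 and AT2G28490 at -2.44 ± 0.55, and for 5 without abi3-5 blotter replicate 3. It was negative for 2 of 4 oil body genes, or 3 adjusted over the list alone, the oleosin gene AT3G18570 (-2.13 ± 0.46) and AT3G01570 (-1.71 ± 0.47, adjusted p = 0.0300). The AT3G01570 call was lost over every feature (adjusted p = 0.0584) and without any 1 of 10 arrays (0.0504 to 0.0701, the last without abi3-5 developing replicate 3), which leaves 1 of 4. Camera's call for the oil body list was lost with an estimated correlation (adjusted p = 0.320), and the list did not pass with fry (adjusted p = 0.0779).

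GID1C (-1.99 ± 0.40), GID1A (-1.94 ± 0.22), AIM1 (-1.48 ± 0.19) and PDC2 (-1.77 ± 0.22) had negative interactions, while LHB1B2 (3.38 ± 0.51), PSBY (2.18 ± 0.36) and FaTA (1.97 ± 0.28) had positive ones. The seed coat markers ARA12 (-1.93 ± 0.41) and AT2G22900 (1.21 ± 0.21) went opposite ways. By the naming rule the largest positive interactions were those of AT2G27570 (5.73 ± 0.42), AT1G22330 (5.59 ± 0.70), AT5G45670 (5.57 ± 0.68), EXPA15 (4.96 ± 0.46), ATGSTF13 (4.87 ± 0.61) and AT5G45650 (4.87 ± 0.67). AT2G27570 was at 3.08 ± 0.33 in developing abi3-5 seeds already (SD, n = 3), against 8.99 ± 0.54 in developing Ler seeds. The largest negative interactions were those of AT1G68240 (-4.69 ± 0.64), AT2G36970 (-4.68 ± 0.51), AT5G54000 (-4.63 ± 0.52), M17, M10 and UGT76E12 (-3.93 ± 0.40).

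In all, 1023 genes had a positive and 1054 a negative interaction, and 865 and 717 of them by 2-fold or more. Without the 4 arrays numbered 3, an alternative chosen after seeing the data, these counts were 1610 and 1638. Without abi3-5 developing replicate 2 the second count was 694, and without Ler blotter replicate 2 it was 670. Camera called LEA (median -1.63, adjusted p = 2.76e-09), heat shock (-1.98, adjusted p = 6.20e-05), storage (-2.39, adjusted p = 0.000356), oil mobilisation (-0.78, adjusted p = 0.00294), gibberellin receptor (-1.94, adjusted p = 0.0105), oil body (-1.92, adjusted p = 0.0159) and other late seed genes (-1.57, adjusted p = 0.0312) lower and photosynthesis (0.85, adjusted p = 0.00294) higher. With an estimated correlation none held, with an adjusted p = 0.135 for the LEA and gibberellin receptor lists, 0.173 for heat shock, storage, oil mobilisation and photosynthesis and 0.320 for the others. The call for other late seed genes was lost without replicate 3 of Ler developing (adjusted p = 0.0518), abi3-5 developing (0.0557) or Ler blotter seeds (0.0527), and among genes above the median level it was lost (0.0995) as was that for oil body genes (0.0724). The call for other late seed genes was lost too with quantile normalization (adjusted p = 0.0605), and the list did not pass with fry (adjusted p = 0.0779). Of the 3 other late seed genes BETA-VPE passed (-1.57 ± 0.45, adjusted p = 0.0359), a call lost under quantile normalization (0.0591), over every feature (0.0680) and without any 1 of 9 arrays (0.0527 to 0.0779, the last without Ler blotter replicate 2). Cell wall loosening did not pass (adjusted p = 0.303), but did without abi3-5 blotter replicate 3 (0.0416). Seed coat, endosperm and fruit wall markers did not pass as lists with camera (adjusted p = 0.814, 0.652 and 0.303) or fry (0.429, 0.429 and 0.207).

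**Figure D3:**
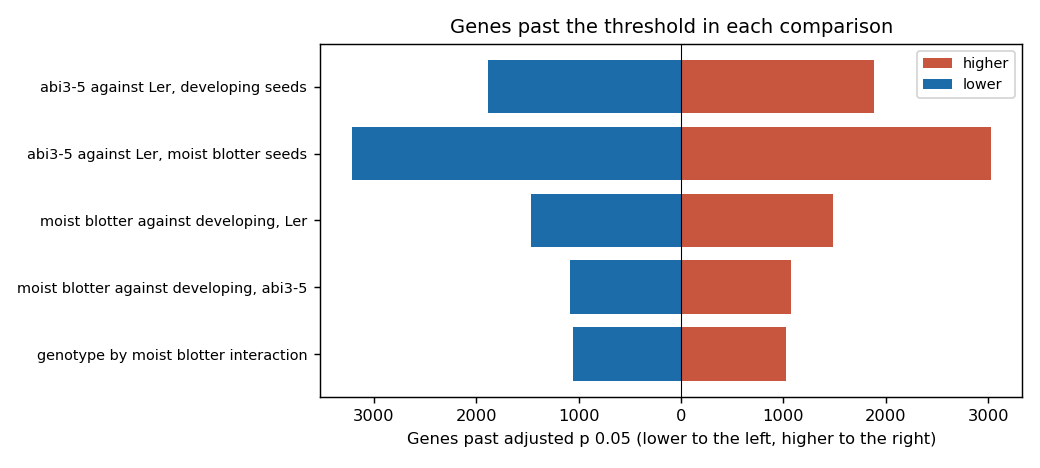
Number of genes past the threshold in each comparison on the x axis, with genes that were lower to the left and genes that were higher to the right. The bars run from 1023 higher genes in the interaction to 3214 lower genes between the genotypes in blotter seeds.

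The genotype differences of developing and blotter seeds, which share no arrays, were correlated across the 16550 genes (Pearson's r 0.71, Spearman's rho 0.59). Genes are not independent replicates, and no p is given. Of the called genes 1407 were higher in abi3-5 in both kinds of seed, where independent lists would share 344.5, and 1260 were lower in both, where they would share 365.5. AT2G42560, AT2G25890, AT2G21720 and BGLU19 were among the largest negative differences in both. Opposite calls were made for 106 genes.

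Developing abi3-5 seeds were also set against blotter-kept Ler seeds, both relative to the same 3 developing Ler arrays. Across genes the differences correlated with r 0.31 and rho 0.28. Simulated unchanged groups against such shared arrays gave r 0.50, above the observed value. The covariance was 0.155 against 0.0298 in the simulation, a difference of 0.126. Both differences were positive for 503 called genes and negative for 592, where independent lists would share 169.6 and 166.5, and 318 genes were called in opposite directions. Part of these excesses may come from the shared arrays. ICL, PSBW and CHLM rose in both comparisons, whereas AT1G52560 and AT1G53540 were lower in developing abi3-5 seeds and rose in Ler on the blotter.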

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

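The tests of a maturation stage and of a trend as the whole cause in the arrays numbered 3 and all counts of other splits were chosen after the results they bear on had been seen, as was leaving out the arrays numbered 3, and the margins of error for these tests were set after their values were seen. The blotter difference was not the same in both genotypes for 8 gene lists, by the camera test of the interaction. Median interactions were -2.39 for seed storage proteins, -1.98 for heat shock proteins, -1.94 for the 3 gibberellin receptor genes, -1.92 for oil body proteins, -1.63 for LEA proteins, -1.57 for other late seed genes, -0.78 for oil mobilisation and 0.85 for photosynthesis. None of these list calls held with an estimated correlation between genes, where the lowest adjusted p = 0.135, and with fry the oil body and other late seed lists did not pass (adjusted p = 0.0779 for both).

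Of the genes named in the text, the following also had a blotter difference that differed between the genotypes by limma's interaction test. Negative log2 interactions, meaning a lower blotter difference in abi3-5 than in Ler, were found for AT1G68240 (-4.69), AT2G36970 (-4.68), AT5G54000 (-4.63), M17 (-4.58), M10 (-4.16), UGT76E12 (-3.93), AT5G24490 (-3.92), AT2G29500 (-3.67), AT1G52560 (-3.62), AT1G03890 (-3.50), UGT73B4 (-3.33), AT1G53540 (-3.12), AT3G15670 (-2.98), AT3G58450 (-2.83), AT5G43770 (-2.81), AtLEA4-1 (-2.81), PDF1.4 (-2.73), AT2G28490 (-2.44), AT2G18540 (-2.39), AT3G18570 (-2.13), AT1G65500 (-2.02), GID1C (-1.99), GID1A (-1.94), ARA12 (-1.93), PDC2 (-1.77), AT3G01570 (-1.71), AT2G37660 (-1.69), BETA-VPE (-1.57), AIM1 (-1.48) and ICL (-0.85). The ICL call was lost without replicate 2 of developing Ler (adjusted p = 0.0543), replicate 1 or 2 of developing abi3-5 (0.0577 and 0.0675) or replicate 1 or 2 of Ler blotter seeds (0.0650 and 0.0647).

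Positive interactions were found for AT2G22900 (1.21), NAI1 (1.12), FOLB3 (1.59), PSAN (1.95), PSAE-1 (1.955), FaTA (1.97), JAL33 (2.03), PSBY (2.18), AT3G60730 (2.19), BGLU21 (2.37), CP1 (2.52), LHB1B2 (3.38), AT5G16240 (3.57), AT5G45950 (4.02), AT5G26260 (4.23), AT2G45180 (4.37), AT5G22810 (4.73), AT1G06360 (4.86), AT5G45650 (4.87), ATGSTF13 (4.87), EXPA15 (4.96), AT5G45670 (5.57), AT1G22330 (5.59) and AT2G27570 (5.73).

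Features that name several genes or none here, 21686 in all, entered the alternative over every feature and no other comparison. Between the genotypes 4629 of them passed the threshold in developing seeds, 3254 higher and 1375 lower in abi3-5, and 7279 in blotter seeds, 4625 higher and 2654 lower. Among the named genes the calls were 1886 higher and 1882 lower in developing seeds and 3023 and 3214 in blotter seeds.

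The 4 arrays numbered 3 deviated from their group means in the same direction, with correlations between 0.17 and 0.39 over their 6 pairs. In each group the array numbered 3 had the narrowest middle range of levels and the lowest array weight (0.28 to 0.60). In Ler blotter seeds its 25th percentile was 4.12 against 3.83 and 3.78, and its 75th 7.74 against 7.92 for both others. Deviations of these arrays correlated with gene length at -0.15 to -0.36 (Spearman). The cause was not tested. After each array's trend on gene length and mean level was removed, the lowest of the 6 correlations was 0.103 with a bootstrap error of 0.00899, so for that pair the trend cannot be told apart from another shared cause at the bound of 0.1. The other 5 stayed over it by more than their errors, up to 0.283. These errors come from resampling genes, which are not independent replicates. They therefore do not decide whether the trend is the whole cause. Seeds of another maturation stage may also contribute, but whether earlier or later was not tested. The storage, oil body, LEA and other late seed genes lay above matched random lists in 2 of the 4 arrays, both of abi3-5 (0.19 and 0.64 at the median). In the Ler arrays they did not (0.02 and 0.04). Genes of these lists vary together, which random lists do not copy, so a list can leave that range easily. Deviations in a group sum to 0, so a high replicate 3 can equally mean low values in the other arrays. These values do not decide about the stage. A shared day or plant batch is not given in the sources used here.

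Other splits of the arrays were counted for each comparison. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each of the 4 comparisons 1 of the 10 splits, the real one, gave as many genes. The real counts were 3768, 6237, 2952 and 2156, in the order developing seeds, blotter seeds, Ler and abi3-5, and the highest of the other splits gave 0, 0, 1 and 0 genes. Every other split mixes the groups compared and leaves their difference in the residual spread. It so gives few genes by construction, and these counts say nothing about chance. For the interaction 2 of 100 regroupings within genotypes, the real one included, gave at least the real 2077 genes, but this count says nothing about chance. The 98 regroupings that mixed developing and blotter arrays kept the blotter difference in their residual spread, with median residual SDs of 0.264 to 0.308 against 0.252 for the real grouping, and so give few genes by construction, at most 1307. The only other unmixed regrouping exchanged all blotter and developing arrays of Ler, gave the highest other count of 3120 genes and measures the blotter difference common to both genotypes.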

How the results depend on the processing

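Leaving out the 4 arrays numbered 3 was chosen after the data were seen, and the other alternatives were fixed before. Of the alternatives for the counts of genes, 203 of 228 stayed within 1.5 times the reported count and 25 did not. Over every feature, where more features are tested, higher and lower counts were 4985 and 3078 between genotypes in developing seeds, 7522 and 5656 in blotter seeds, 2953 and 2693 in Ler on the blotter, 1865 and 1643 in abi3-5, and 1622 and 1601 for the interaction. With array weights, lower genes numbered 2928 and 5127 between genotypes in developing and blotter seeds, and higher and lower genes 2440 and 2277 in Ler, 2471 and 2733 in abi3-5, and 2295 and 2444 for the interaction. Without the arrays numbered 3 the interaction gave 1610 and 1638. The cause of these differences was not tested. Leaving out 1 array at a time gave ranges, higher then lower, of 1370 to 2058 and 1342 to 2066 in developing seeds, 2681 to 3133 and 2693 to 3390 in blotter seeds, 1011 to 1623 and 1130 to 1616 in Ler, 650 to 1367 and 714 to 1205 in abi3-5, and 751 to 1431 and 670 to 1224 for the interaction. The correlation of genotype differences between developing and blotter seeds was 0.72 above the 25th percentile of level, 0.751 above the median, 0.691 over every feature, 0.682 without the arrays numbered 3 and 0.673 to 0.719 with 1 array left out. The correlation with the blotter difference in Ler ranged from 0.295 to 0.363 with 1 array left out. With the replicate number as a block, 2233 genes were higher and 2408 lower in developing seeds, where the same-number correlations were 0.23, -0.05 and 0.22 and 4 of 6 arrays correlated best with their own number. The block changed no list call and moved no count over all genes by over 1.5 times, and the counts within lists that it moved and that are printed are given beside them. For lists, 46 of 1405 alternatives lost a call, 9 gained one and 0 turned in direction, and for named genes 101 of 3726 lost a call and 0 turned. The named genes were picked for passing the threshold, many with the largest differences, so a turn was unlikely from the start. Leaving out an array of a group not compared also leaves the difference itself unchanged. The share for named genes therefore says little about how stable their calls are. Genes with a mean log2 level near the low end of the scale limit what can be seen, since signal over background was not used.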

Other observations

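The plastid, endoplasmic reticulum body and gene family lists here were chosen after the data were seen, as were the tests of bright features and of length and level in plastid genes and the test of 17 abi3-5-high genes, and the margins of error for these tests were set after their values were seen. Plastid-encoded transcripts were higher in abi3-5. Of 63 measured genes 36 were higher in developing seeds and 55 in blotter seeds, and 0 were lower in either, with medians of 0.61 and 0.88. With an estimated correlation the adjusted p = 0.0306 and 0.0388. In developing seeds 15 of 17 genes of the plastid RNA polymerase and ribosome (rpo, rps and rpl) were higher (median 1.21, rpoB 2.07 ± 0.19 SE). Of photosystem genes (psa and psb) 1 of 18 was higher (median 0.30, psbA 0.03 ± 0.12). In blotter seeds these counts were 16 of 17 and 13 of 18. With an estimated correlation the photosystem class did not pass in developing seeds (adjusted p = 0.323), nor did either class in blotter seeds (0.0775 for each).

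A list of 10 genes was grouped here with endoplasmic reticulum bodies, compartments that hold beta-glucosidases. Not all of them encode proteins of these bodies. In abi3-5, 9 of 10 were higher in developing seeds and 10 of 10 in blotter seeds. No list test was run on these 10 genes. As they were chosen after the data were seen, the counts describe them alone. NAI2 differed by 7.17 ± 0.85, PYK10 by 5.41 ± 0.70, BGLU21 by 2.34 ± 0.29, NAI1 by 1.93 ± 0.24 and JAL33 by 0.75 ± 0.20 in developing seeds. JAL33 was at most 3.85 on the developing arrays, under the 25th percentile of mean levels (3.89).

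Families were taken from the letters of gene symbols, and 36 had at least 8 tested members. Over the 5 comparisons 15 family calls passed camera, adjusted within each comparison, and 1 of these held with an estimated correlation, that of TRM genes, which were lower in Ler on the blotter (8 of 15, median -0.73, adjusted p = 0.000158, and adjusted p = 0.0427 with an estimated correlation). In Ler on the blotter UGT genes, which encode glycosyltransferases, were also higher (18 of 51, 3 lower, adjusted p = 0.00193), and IAA (3 of 8, adjusted p = 0.0149) and GH genes (7 of 24, adjusted p = 0.0219) lower, with an adjusted p = 0.134, 0.134 and 0.618 with an estimated correlation. ALDH genes were higher in developing abi3-5 seeds (4 of 8, adjusted p = 0.00761, and 0.792 with an estimated correlation) and SCPL genes in abi3-5 blotter seeds (14 of 32, 2 lower, adjusted p = 0.0481, and 0.245), where the SCPL median was 0.08 and -0.04 after median centring. In abi3-5 on the blotter CLE (4 of 16, adjusted p = 0.0324) and SCPL genes (7 of 32, 1 lower, adjusted p = 0.0436) were higher and ATG genes lower (4 of 8, adjusted p = 0.0351), all lost with quantile normalization (adjusted p = 0.0531 for each) and with an estimated correlation (0.429, 0.429 and 0.771). Interactions were positive for TRM (5 of 15, adjusted p = 0.00125, and 0.0799 with an estimated correlation), GH (5 of 24, 0.00631, and 0.386), IAA (2 of 8, 0.0161, and 0.217) and CLE genes (5 of 16, 0.0296, and 0.365) and negative for ATG (2 of 8, 0.0110, and 0.373) and UGT genes (14 of 51, 1 positive, 0.0401, and 0.365). With quantile normalization the CLE and UGT interactions did not pass (adjusted p = 0.0507 for both), nor did that of UGT after median centring (0.0535).

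The median difference between genotypes in developing seeds was 0.912 higher for rpo, rps and rpl genes than for psa and psb genes. Bright features that no longer follow the level may hide differences of photosystem genes. Among 11 and 5 genes with a mean level of at most 12.4 the class difference was 1.08 (exact permutation p = 0.00962), no smaller than over all members. After a trend on gene length and mean level was removed the class difference was 0.595 with a bootstrap error of 0.229 (permutation p = 0.00563). Both permutations and the bootstrap resample genes, which are not independent replicates, and the classes were chosen after the data were seen. These values therefore do not decide whether bright features or the trend account for the whole class difference or most of it. In blotter seeds the class difference was 0.207.

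In 1 developing Ler array, replicate 1, the 5 genes of the endoplasmic reticulum body list that are over 3 log2 units higher in abi3-5 lay 1.66 above the other developing Ler arrays at the median. Lists matched on length and level gave -0.14 to 0.32. The 5 genes come from a list chosen after the data were seen, and such genes tend to lie outside random lists whatever the cause. The comparison therefore does not decide about a trend with length and level. A small share of abi3-5 RNA in that array, 2.44 to 6.21%, may be an explanation. It predicts a median rise of 0.344 in 81 other abi3-5-high genes, where 0.310 was found with a bootstrap error of 0.0983, and this leaves it open. In the 17 genes with a predicted rise over 0.5 the median rise was 0.734 against a prediction of 0.631. The prediction and the rise both use the levels in replicates 2 and 3. Genes picked for a high prediction therefore tend to show a rise without any mixing, and this value does not bear on the mixing. A programme of genes that vary together in Ler seeds stays open too, since in Ler blotter seeds 4 of these 5 genes were lower in replicate 3 than in replicates 1 and 2 (NAI2 6.32 against 8.76 and 8.46, PYK10 7.53 against 10.77 and 10.34, AT1G54010 7.26 against 8.90 and 8.92, AT3G20370 4.17 against 6.81 and 6.27), and AT3G32980 was not (4.75 against 4.37 and 5.01).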
